A study of Homo sapiens with 20 samples.

How the data were processed

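RNA from differentiated Caco-2 cells was profiled on 20 Affymetrix HG-U133 Plus 2.0 arrays, 14 in the probiotic set, labelled from 5 µg of RNA, and 6 in the E. coli set, labelled from 1 µg, per the labels' protocols. Lactobacilli and Bifidobacterium were grown in MRS broth and E. coli in LB broth with 1% glucose, per the labels' protocols, and no group with broth alone was analysed here. The deposited values are log2 probe-set summaries made by the authors with RMA, per the submitters' processing notes. The version, and whether both sets were normalized together, are not given in the sources used here. Scanner files were not used here, so background correction and detection calls could not be varied, and precision is limited by the number of arrays.

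Of 54675 probe sets, 41091 carried 1 gene symbol in the platform annotation, 1801 several and 11721 none, besides 62 control probe sets. Symbols were updated through Entrez identifiers to the RefSeq table of assembly GRCh38.p14, except for 54 probe sets whose identifier had no match and kept the annotated symbol. No coordinates are printed because the files name no genome build. Each of 19775 genes was represented by the probe set with the highest mean over all 20 arrays, leaving out cross-hybridising probe sets with the suffix _x_at where the gene had others, and 10523 genes had more than 1 probe set. Genes whose mean over the arrays of a fit reached the 40th percentile of all named genes were tested, which left 11865 in each comparison, and the 40th percentile is the floor named in the results.

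Groups were taken from the labels. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on mean signal), and p-values were adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. Co-cultures and supernatants were compared with 8 h medium in 1 fit over the 14 arrays of the probiotic set, so that groups of 2 shared an estimate of the spread. Differences among strains were tested with moderated F-tests in that fit, and whether they depend on format with the interaction of strain and format. E. coli supernatant was compared with its medium over the 6 arrays of its set. Supernatants against 24 h medium, and the media against each other, were tested over all 20 arrays, where array set, RNA input and, for the media, time cannot be separated. Genes called in the same direction against both media were counted. Standard errors are those of the fits.

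Gene lists, 35 with 847 distinct genes of which 763 had a named probe set, were fixed before the data were examined, as were the tests, the alternatives and the rule for genes that are named. A list needed 5 measured genes. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. They were also tested with fry, which asks whether a list has a net shift, without setting it against other genes. Named by the rule were, per comparison, the 8 largest rises and 8 largest falls among called genes whose treated arrays all lie on 1 side of the controls, up to 4 called members of each list with the lowest adjusted p, the 12 called genes with the widest range in each F-test, and CXCL8, CCL20, TNFAIP3, NFKBIA, PTGS1, PTGS2, TJP1, OCLN and CLDN1 whatever their values. Pairwise contrasts between strains were added after the values were seen.

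Correlations of changes across genes that share control arrays were set beside 100 simulations of unchanged groups against the same controls, and beside the overlap that independent lists would have. Alternatives were no filter, a filter at the 60th percentile, eBayes without a trend, only the groups compared in the fit, all 20 arrays in 1 fit for E. coli, quantile normalization of all arrays together, every probe set tested on its own, the other probe sets of named genes, the replicate number of the labels as a block, and leaving out each array in turn. Leaving out 1 of 2 arrays assumes that the remaining one varies like the other groups. The fits were tested on simulated data with 200 changed genes among 11865. For the NCFM co-culture 67.2% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold were called, with 9 false calls (4.84% of calls). For E. coli supernatant the shares were 68.7%, 100% and 100%, with 17 false calls (8.67% of calls). Simulated noise was independent between genes, and far more than 200 genes were called in the real comparisons. These rates therefore need not hold for the data.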

Results

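Gene expression was measured on human whole-genome expression arrays in Caco-2 cells, a human colon carcinoma line that takes on features of small intestinal enterocytes when it is kept confluent. The cells had differentiated on inserts for 5 days before treatment. In the probiotic set of 14 arrays, each of 7 groups had 2 arrays. Cells received medium alone for 8 h, live Lactobacillus acidophilus NCFM, Bifidobacterium lactis 420 or Lactobacillus salivarius Ls-33 for 8 h at 20 to 100 bacteria per Caco-2 cell, or the cell-free culture supernatant of 1 of these strains for 24 h at 10% of the medium volume. In the E. coli set of 6 arrays, cells received medium alone or 5% cell-free supernatant of enterohaemorrhagic Escherichia coli O157:H7 for 24 h, with 3 arrays in each group. The medium controls therefore differ in time and in array set, and no group received uninoculated bacterial broth. The series states that the samples of the probiotic set were analysed in duplicate, so the 2 arrays of a group may come from 1 culture, and p-values there measure only the spread between arrays.

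Median log2 signal lay between 2.66 and 2.72 in all 20 arrays. Arrays of 1 group correlated at r = 0.994 to 0.997 across probe sets, which are not independent replicates, over 13 pairs. The difference between the 3' and 5' control probe sets of beta-actin, a measure of RNA integrity and labelling, was 0.84 ± 0.054 (SD, n = 2) with 8 h medium. It was 1.40 ± 0.20 with NCFM cells, 1.18 ± 0.13 with B. lactis 420 cells and 1.24 ± 0.020 with Ls-33 cells, and 1.05 to 1.09 in the means of the 3 supernatant groups. In the E. coli set it was 2.00 ± 0.15 (SD, n = 3) with medium and 2.17 ± 0.054 with supernatant. The same difference for GAPDH was -0.035 to 0.020 in the 8 h medium arrays, 0.016 to 0.106 in the co-culture arrays and -0.023 to 0.035 in the probiotic supernatant arrays. In the E. coli set it was 0.117 to 0.223 with medium and 0.246 to 0.337 with supernatant, so this sign of RNA quality moved with the E. coli treatment. The 5' control probe set of 18S rRNA read 12.4 to 13.5 in the probiotic set and 5.78 to 6.56 in the E. coli set, so both measures separated the sets.

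**Figure D1:**
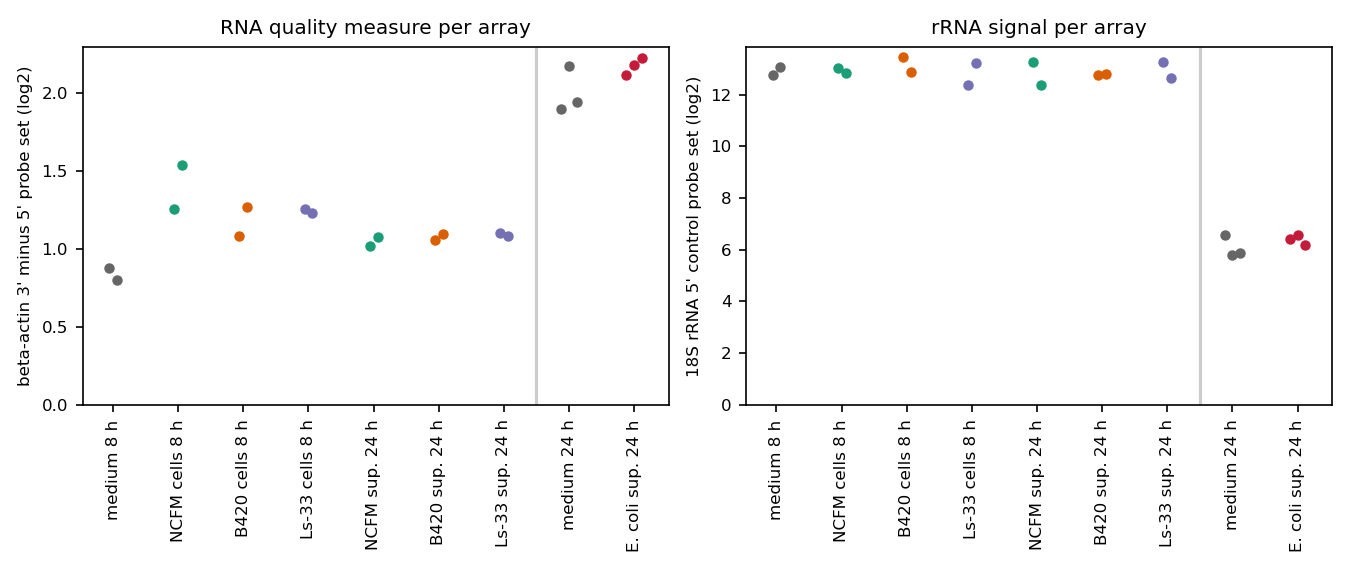
Left, difference between the 3' and 5' beta-actin control probe sets (log2) for each of the 20 arrays by group; right, log2 signal of the 18S rRNA 5' control probe set. Each point is 1 array, and a grey line parts the probiotic set from the E. coli set; all 6 arrays of the E. coli set lie at 1.90 or above on the left and at 6.56 or below on the right.

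What live bacteria did to the epithelial cells within 8 h was asked by comparing each co-culture with 8 h medium. SLC2A5 (probe set 204430_s_at), the intestinal fructose transporter, dropped from 9.07 ± 0.11 (log2, SD, n = 2) in medium to 4.43 ± 0.12 with NCFM, 4.49 ± 0.16 with B. lactis 420 and 4.21 ± 0.60 with Ls-33. These are falls of 24.9-fold, 23.9-fold and 29.1-fold, with limma adjusted p-values of 4.59e-13, 5.12e-13 and 1.46e-13. The water and glycerol channel AQP10 was lower by log2 changes of -3.45, -3.75 and -4.13 in the same order. SLC51A, a subunit of the basolateral bile acid exporter, changed by -3.65, -3.42 and -3.71, and TNFSF10, which encodes the death ligand TRAIL, by -4.41, -4.21 and -4.37. LGALS14, a galectin gene, changed by -4.35, -4.47 and -5.28. Standard errors of these changes were between 0.11 and 0.20, and in every case both co-culture arrays lay below both medium arrays. In all, 1350 genes were lower and 1149 higher with each of the 3 strains, and 61 genes were called in opposite directions by some.

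The fixed list of lipoprotein assembly and lipid absorption genes was lower with every strain. With NCFM 14 of 20 measured members were lower and 0 higher (14 and 1 adjusted over the list alone); the lower and higher counts were 14 and 1 (15 and 2) with B. lactis 420 and 14 and 2 (14 and 2) with Ls-33. MTTP, the triglyceride transfer protein of lipoprotein assembly, fell by 8.41-fold, 7.79-fold and 6.65-fold, and APOA4 by 7.71-fold, 6.81-fold and 6.03-fold. For the 23 measured brush border and absorption genes the lower and higher counts, with those adjusted over the list alone in brackets, were 17 and 2 (17 and 3) with NCFM, 15 and 2 (15 and 2) with B. lactis 420 and 15 and 3 (15 and 3) with Ls-33. The chloride and bicarbonate exchanger SLC26A3 changed by -1.74, -1.91 and -2.03, and the peptidase DPP4 by -0.89, -0.87 and -0.68. Of 5 measured bile acid genes, 4, 4 and 5 were lower and none higher, also adjusted over the list alone, among them the ileal bile acid binding protein FABP6 at -1.19, -1.40 and -1.62. For 35 hypoxia and glycolysis genes the counts, in the same form, were 26 and 2 (27 and 2), 28 and 0 (28 and 1) and 25 and 2 (25 and 2), and NDRG1 changed by -1.30, -1.34 and -1.36. Heat shock genes went the other way, with higher and lower counts among 19 of 8 and 2 (10 and 2), 10 and 2 (13 and 2) and 12 and 1 (12 and 1). The chaperone gene HSPH1 rose by 1.24, 1.29 and 1.43. Camera, a test of a list against all other genes, called these 5 lists for every strain, with adjusted p from 1.21e-13 to 0.00373, and all 15 calls held with a correlation estimated from each list. The actin 3' to 5' difference was higher in all 6 co-culture arrays than in both medium arrays.

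**Figure D2:**
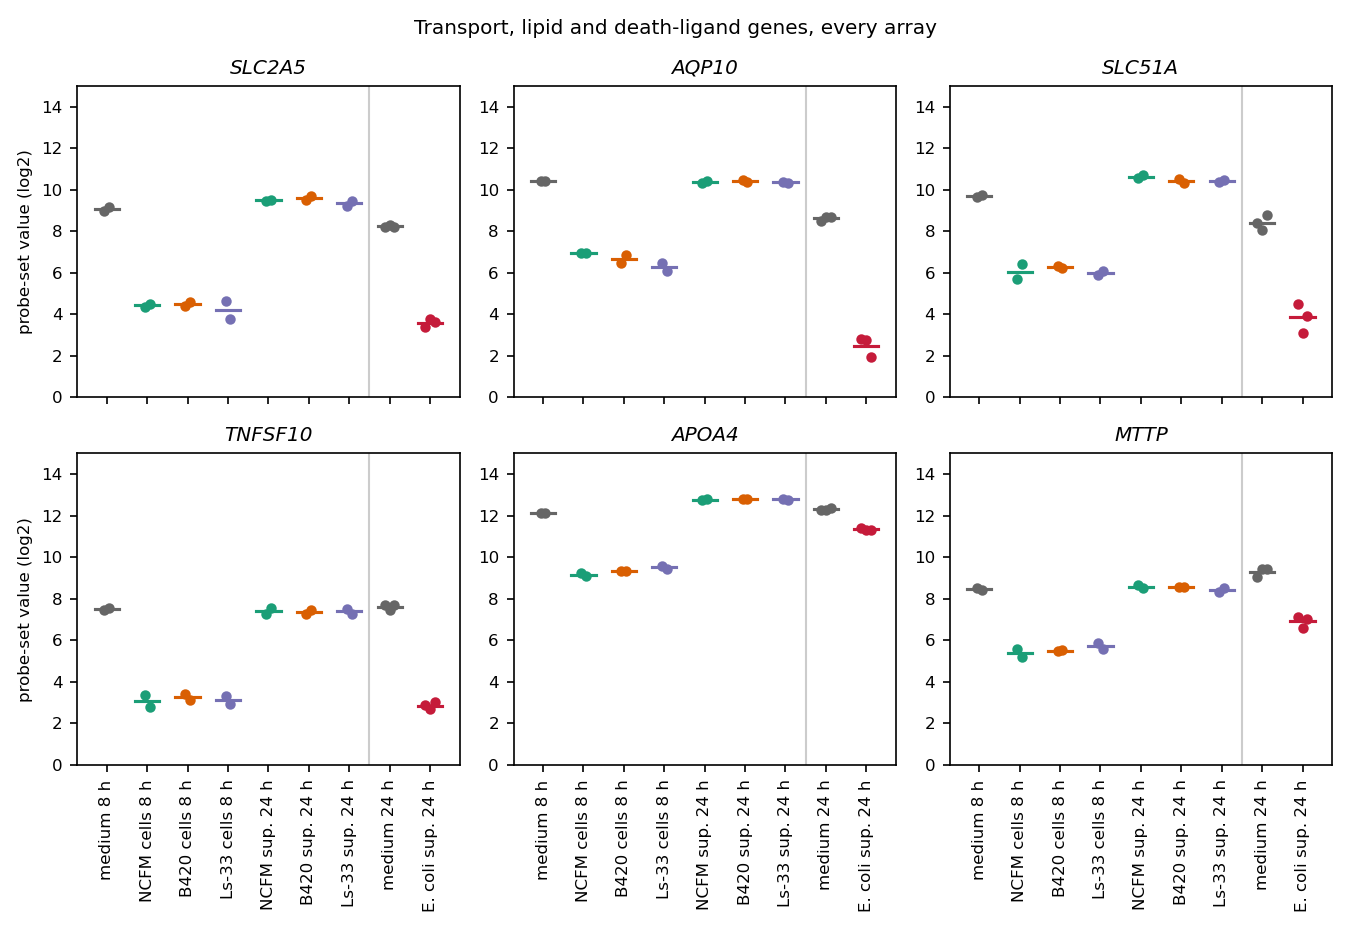
Log2 probe-set values of 6 genes in each of the 20 arrays by group. Points are arrays, short bars are group means, and the grey line parts the 2 array sets; SLC2A5 fell by 4.64, 4.58 and 4.86 with the 3 co-cultures and by 4.63 with E. coli supernatant on the log2 scale, and averaged 9.07 ± 0.11 in 8 h medium against 9.49 ± 0.027, 9.62 ± 0.15 and 9.36 ± 0.17 in the probiotic supernatants (SD, n = 2).

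The largest rises with L. acidophilus NCFM included DHRS2, RSRP1 and TAF1D. DHRS2 (probe set 214079_at), a short-chain dehydrogenase, rose 6.22-fold (log2 change 2.64 ± 0.20 SE, limma adjusted p = 4.18e-09) and RSRP1 (probe set 209007_s_at) 5.94-fold (2.57 ± 0.10, adjusted p = 1.44e-13). TAF1D, a subunit of the RNA polymerase I selectivity factor, rose by 2.02, and the snoRNA host gene SNHG19 by 1.99. Of the NF-kB and chemokine list, 4 of 20 measured members were higher and 4 lower (4 and 4 adjusted over the list alone), and camera gave an adjusted p of 0.573. Among these, NFKBIZ, an atypical IkB protein, rose by 1.52 and the adhesion receptor ICAM1 changed by -1.32. Immediate early genes were lower as a list. There 13 of 30 measured members were lower and 2 higher (14 and 4 adjusted over the list alone), with EGR1 at -1.86, camera adjusted p = 0.00169 and adjusted p = 0.0427 with an estimated correlation. The unfolded protein response list was lower too, where 18 of 25 measured members were lower and 2 higher (18 and 3 adjusted over the list alone). HERPUD1, of endoplasmic reticulum degradation, changed by -1.14, but its other probe set went the other way, without a call. Of TGF-beta and matrix genes 10 of 21 measured members were lower and 1 higher (11 and 2 adjusted over the list alone), including ID1 at -1.06, with adjusted p = 0.00373. limma called 4186 of 11865 genes at adjusted p under 0.05, 1997 higher and 2189 lower, of which 480 changed at least 2-fold. Directions depended on the probe set more often than with the other strains. Of 1579 genes with at least 2 called probe sets, 16.7% had called probe sets of opposite direction, against 9.80% with B. lactis 420 and 8.54% with Ls-33 cells.

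Bifidobacterium lactis 420 raised most measured members of the NF-kB and chemokine list. The probe set named for the microRNA gene MIR146A (232504_at), which does not read the mature microRNA, rose from 2.21 ± 0.10 to 8.28 ± 0.053 (log2, SD, n = 2), by a log2 change of 6.07 ± 0.17 (SE, limma adjusted p = 7.76e-16). Its medium value lay under the filter's floor of 2.74, so the size of its fold is uncertain. The scavenger receptor OLR1 (probe set 210004_at) rose 20.0-fold, the antiprotease elafin, PI3, 13.3-fold, and complement C3 10.9-fold. TNFRSF9, a TNF receptor family member, rose 7.04-fold and TNFAIP3, a negative regulator of NF-kB, 6.85-fold. The chemokine CCL20 rose from 9.53 ± 0.0045 to 12.29 ± 0.081, and CXCL8, whose medium value also lay under the floor, by 2.36 ± 0.25 (SE, adjusted p = 3.99e-07). In the NF-kB and chemokine list 14 of 20 measured members were higher and 0 lower (14 and 0 adjusted over the list alone), with camera adjusted p = 8.09e-10 and adjusted p = 0.00613 with an estimated correlation. Unfolded protein response genes were lower, where 14 of 25 measured members were lower and 4 higher (14 and 4 adjusted over the list alone), camera adjusted p = 3.82e-04. Of the immediate early list 11 of 30 measured members were lower and 2 higher (11 and 2 adjusted over the list alone). Its camera adjusted p was 0.0470, but adjusted p = 0.119 with an estimated correlation. The number called was 4184, 2173 higher and 2011 lower, with 480 at 2-fold or more.

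Lactobacillus salivarius Ls-33 raised most measured members of that list too. OLR1 rose 52.9-fold (log2 change 5.73 ± 0.16 SE, limma adjusted p = 1.33e-15), CEACAM7, an adhesion molecule of colon epithelium, 31.8-fold, and PI3 28.5-fold. The inflammatory caspase CASP5 rose 27.4-fold, LRG1 24.2-fold, the tryptophan catabolic enzyme KYNU 21.0-fold and C3 19.1-fold. CXCL10, an interferon-inducible chemokine with medium values under the floor, rose by 4.13 ± 0.16 (SE, adjusted p = 1.28e-13). CXCL8 rose by 3.30 and CCL20 by 2.60. Of the NF-kB and chemokine list 13 of 20 measured members were higher and 1 lower (13 and 1 adjusted over the list alone), with camera adjusted p = 9.45e-09 and adjusted p = 0.00884 with an estimated correlation. Cell cycle genes were lower: 22 of 40 measured members were lower and 2 higher (24 and 2 adjusted over the list alone), among them CCNB1 at -0.70 and CCND1 at -0.79. Their camera adjusted p was 1.65e-05. limma called 4591 genes, 2301 higher and 2290 lower, of which 570 changed at least 2-fold.

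**Figure D3:**
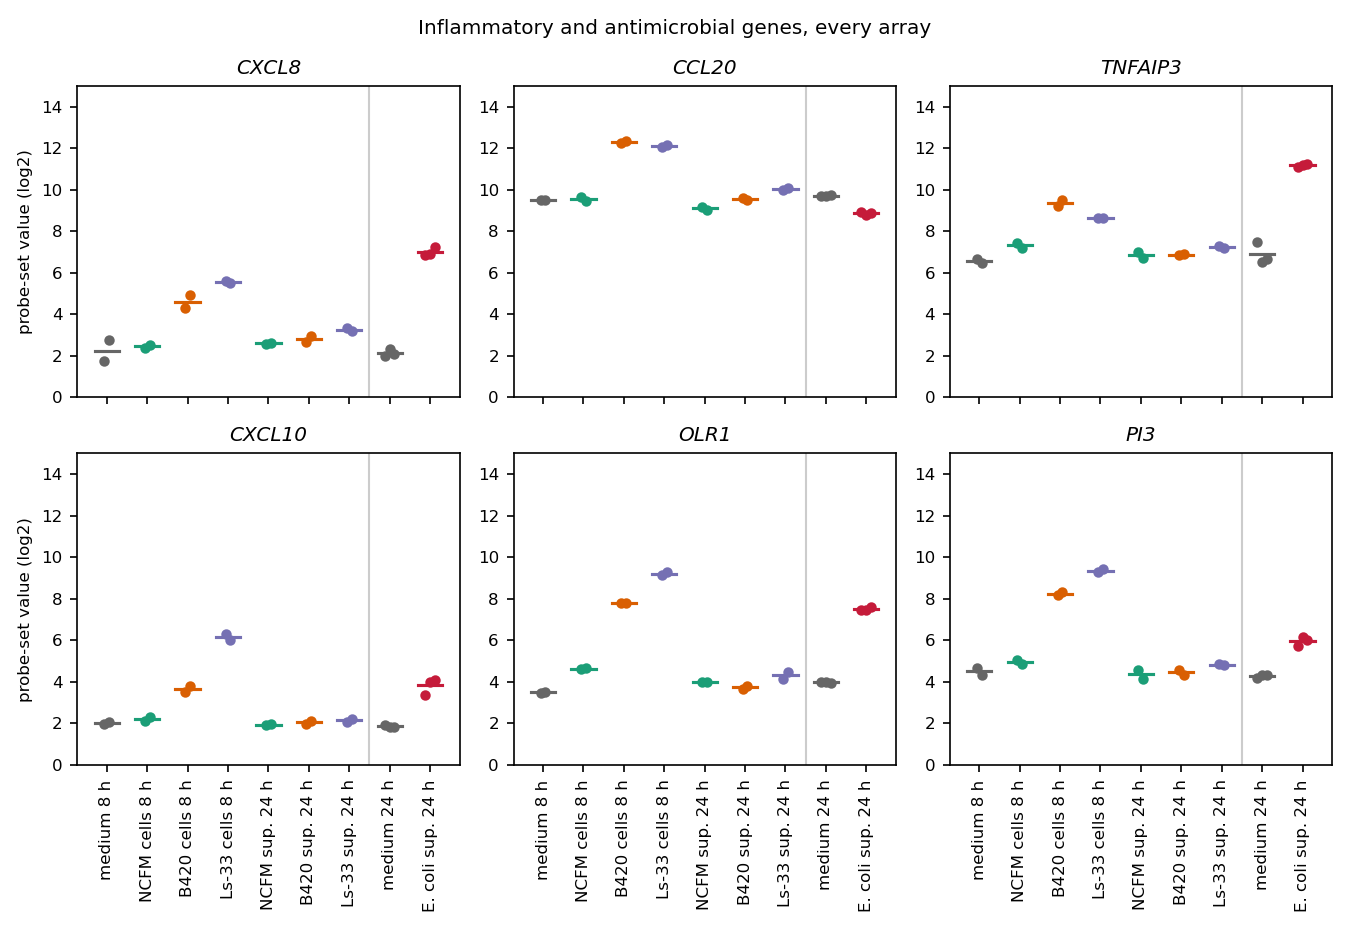
Log2 probe-set values of 6 genes in each of the 20 arrays by group. Points are arrays and short bars group means; CXCL8, under the floor in each medium so that its sizes are uncertain, missed the threshold with NCFM cells (adjusted p = 0.553) and rose by 2.36 and 3.30 with B. lactis 420 and Ls-33 cells and by 4.87 with E. coli supernatant.

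Whether the strains differ from each other was tested with a moderated F-test across the 3 co-cultures. The 12 called genes with the widest range of group means were LRG1, CASP5, OLR1, CEACAM7, PI3, MIR146A, KYNU, C3, CXCL10, ICAM1, CXCL8 and TNFRSF9. Their ranges ran from 4.94 for LRG1 to 3.07 for TNFRSF9 (log2), with limma adjusted p from 2.76e-13 for ICAM1 to 1.06e-07 for CXCL8. Except for MIR146A, which was highest with B. lactis 420, the mean of each was highest with Ls-33 and lowest with NCFM. CXCL10 and CXCL8 lay under the floor with NCFM, so their ranges and places in this order are uncertain. ICAM1 averaged 7.35 ± 0.0018 in medium, 6.03 ± 0.034 with NCFM, 7.84 ± 0.046 with B. lactis 420 and 9.20 ± 0.050 with Ls-33. NFKBIA, the NF-kB inhibitor, ranged by 0.95 with its highest mean in B. lactis 420. Pairwise contrasts, chosen after the values were seen, called 1742 genes between Ls-33 and NCFM, 662 between Ls-33 and B. lactis 420 and 360 between B. lactis 420 and NCFM. In the first of these the NF-kB and chemokine list was higher with Ls-33, where 13 of 20 measured members were higher and 1 lower (16 and 1 adjusted over the list alone), with camera adjusted p = 2.40e-14 and adjusted p = 0.00166 with an estimated correlation. The F-test called 1629 genes, and 404 of the genes that moved the same way with all strains were among them. Without the first Ls-33 co-culture array the count was 845, without the second 945, and without a trend in the variance model it was 942.

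Tight junction genes, which seal the epithelium, changed in both directions, with CLDN3 at -0.69 and CLDN7 at -0.49 with NCFM, and CLDN12 at 0.82 and CGN at -0.65 with Ls-33. OCLN changed by -0.22, -0.27 and -0.21 with NCFM, B. lactis 420 and Ls-33, each past the threshold (adjusted p = 9.18e-04, 9.87e-05 and 0.00129). CLDN1 changed by -0.086 with NCFM, which missed the threshold (adjusted p = 0.357), and rose by 0.32 with B. lactis 420 and 0.46 with Ls-33. TJP1 values differed from medium by 0.12, 0.17 and 0.19, and the calls with B. lactis 420 and Ls-33 were lost without the first medium array, where the differences were 0.098 and 0.11. Its other probe set was called the other way with NCFM. That probe set also went the other way, without a call, with B. lactis 420 and Ls-33. Of the prostaglandin synthases, PTGS1 differed by -0.16, -0.29 and -0.38, none past the threshold, and PTGS2 by 0.22, 0.27 and 0.53 (adjusted p = 0.0935, 0.0351 and 2.59e-04), where the call with B. lactis 420 was lost without the second medium array. The other PTGS2 probe set went the other way, without a call, with NCFM and B. lactis 420. In the tight junction list 8 of 23 measured members were lower and 1 higher (9 and 3 adjusted over the list alone) with NCFM. Camera gave adjusted p = 0.0481 there, and adjusted p = 0.266 with an estimated correlation, and the call was also lost with joint quantile normalization (0.0690) and with a replicate block (0.0509); with B. lactis 420 and Ls-33 it gave 0.340 and 0.711. Of 7 measured fibroblast and leukocyte markers, which these cells should lack, 2, 2 and 3 were higher and 3, 2 and 1 lower, with camera adjusted p = 0.877, 0.514 and 0.988.

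The effect of products released by the probiotics was asked with their supernatants, which had only an 8 h medium control in their own array set. Against 8 h medium, LRRC15 rose 3.63-fold with NCFM supernatant, 3.04-fold with that of B. lactis 420 and 2.68-fold with that of Ls-33, with limma adjusted p = 2.09e-06, 1.10e-05 and 2.93e-05. The aryl hydrocarbon receptor target CYP1B1 rose by 1.31, 1.52 and 1.53, the aldo-keto reductase AKR1B10 by 1.38, 1.59 and 1.24, and TNFRSF9 by 1.29, 1.18 and 1.87. The transcription factor TFEC changed by -1.52, -1.18 and -1.84 and transferrin, TF, by -1.34, -0.92 and -1.62. Standard errors of all these changes were between 0.11 and 0.20. Each of the genes was called in the same direction against 24 h medium of the E. coli set, where LRRC15 was higher by 2.02, 1.77 and 1.59 and TF differed by -6.70, -6.27 and -6.98.

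Immediate early genes were higher as a list with every supernatant against 8 h medium. Time also differs in these comparisons and no group received broth alone, so neither can be told apart from bacterial products here. The actin 3' to 5' difference was also wider in all 6 supernatant arrays (1.02 to 1.11) than in both medium arrays (0.80 and 0.88). With NCFM supernatant 9 of 30 measured members were higher and 0 lower (17 and 0 adjusted over the list alone); with B. lactis 420 the higher and lower counts were 8 and 1 (10 and 1) and with Ls-33 13 and 0 (13 and 0). JUN rose by 0.91, 0.85 and 1.26. Camera gave adjusted p = 9.76e-08, 1.99e-04 and 1.20e-06, and with an estimated correlation adjusted p = 0.0204, 0.103 and 0.0322. For 40 cell cycle genes the lower and higher counts, with those adjusted over the list alone in brackets, were 10 and 0 (14 and 0), 10 and 1 (12 and 1) and 14 and 0 (18 and 2). Their camera adjusted p was 1.48e-05, 0.00272 and 1.40e-05, and adjusted p = 0.0426, 0.108 and 0.0406 with an estimated correlation. The helicase subunit MCM3 changed by -0.79, -0.71 and -0.78. Of the NF-kB and chemokine list 7 of 20 measured members were higher and 0 lower (7 and 0 adjusted over the list alone) with Ls-33 supernatant, at camera adjusted p = 0.00222 and adjusted p = 0.0627 with an estimated correlation. Among 35 hypoxia and glycolysis genes, lower in the co-cultures, the higher and lower counts were 15 and 1 (16 and 2), 11 and 2 (12 and 2) and 19 and 3 (21 and 3). Camera adjusted p was 3.60e-08, 1.79e-04 and 1.20e-06, and adjusted p = 0.0426, 0.108 and 0.0627 with an estimated correlation. Against 24 h medium, where array set and RNA input differ, the higher and lower counts were 18 and 5, 14 and 5 and 15 and 4 of 31 immediate early genes. For hypoxia and glycolysis they were 22 and 5, 21 and 6 and 22 and 5 of 35, and for cell cycle 0 and 36, 0 and 34 and 0 and 36 of 40. Camera called all of these, but with an estimated correlation only cell cycle held (adjusted p = 0.0353, 0.0467 and 0.0292).

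Against 8 h medium limma called 1336 genes with NCFM supernatant, 1802 with B. lactis 420 and 1972 with Ls-33, of which 33, 34 and 59 changed at least 2-fold, and LRRC15, CYP1B1 and TNFRSF9 were among those in all 3. Against 24 h medium the counts were 6632, 6564 and 6583. Genes called in the same direction against both media, such as TFEC, numbered 714, 892 and 1021, and 222, 323 and 329 were called in opposite directions. Lists independent of each other would share 174.9 higher and 196.1 lower genes for NCFM, where 356 and 358 were observed. The corresponding values were 186.5 and 314.3 against 362 and 530 for B. lactis 420, and 286.2 and 258.1 against 548 and 473 for Ls-33. Part of this excess may come from the shared supernatant arrays. Without a trend in the variance model the counts against 8 h medium were 756, 1121 and 1281, and those against both media 437 for NCFM and 584 for B. lactis 420. The counts against 8 h medium depended on single arrays. For NCFM supernatant the count was 768 and 642 without the first and second medium array, and 489 and 863 without the first and second supernatant array. For B. lactis 420 it was 1079 and 876 without the medium arrays and 789 without the second supernatant array, and for Ls-33 it was 1248 and 1098 without the medium arrays and 1236 and 771 without the supernatant arrays. Counts against both media moved likewise. Leaving out the arrays in the same order gave 417, 382, 297 and 464 for NCFM and 518, 462, 587 and 396 for B. lactis 420. For Ls-33 they gave 635 without the second medium array, and 640 and 436 without the first and second supernatant array.

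Among the 3 supernatants, 4 genes differed by the limma F-test, against 951 at an unadjusted p under 0.05. These were the chemokine CCL20 (range 0.93 log2, adjusted p = 6.65e-06), NFKBIZ (0.68, adjusted p = 5.54e-04), SUMF2 (1.04, adjusted p = 0.0118) and CRIM1 (0.43, adjusted p = 0.0164). CCL20 averaged 9.11 ± 0.10 with NCFM supernatant, 9.57 ± 0.065 with B. lactis 420 and 10.04 ± 0.072 with Ls-33. CXCL8 ranged by 0.66 and missed the threshold (adjusted p = 0.617). The count was 9 without the first NCFM supernatant array, 9 without the first of B. lactis 420, and 0 without a trend in the variance model.

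Strain differences depended on whether cells met bacteria or supernatant for 522 genes, by a test of the interaction. The 12 with the largest interaction were CASP5, LRG1, MIR146A, CEACAM7, OLR1, PI3, CXCL10, KYNU, ICAM1, NNMT, C3 and EGLN3, where MIR146A and CXCL10 lay under the floor in every supernatant, so their size and place are uncertain. For CASP5 the interaction was 4.87 on the log2 scale (limma adjusted p = 2.54e-09). Its means were 3.39 ± 0.17, 6.19 ± 0.33 and 8.30 ± 0.049 with NCFM, B. lactis 420 and Ls-33 cells, and 3.54 ± 0.053, 3.38 ± 0.037 and 3.57 ± 0.10 with their supernatants. OLR1, at 4.27, had means of 4.63 ± 0.043, 7.81 ± 9.0e-04 and 9.21 ± 0.093 with cells and 3.99 ± 0.018, 3.74 ± 0.10 and 4.31 ± 0.24 with supernatants. Cells and supernatants also differed in time, so format and time cannot be told apart here. The count of 522 became 331 and 290 without the first and second NCFM supernatant array, 283 and 302 without the first and second Ls-33 co-culture array, and 264 and 262 without the first and second Ls-33 supernatant array. Without a variance trend it was 146.

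The pathogen's products were tested by comparing E. coli O157:H7 supernatant with 24 h medium on 3 arrays each. FBN2, an extracellular fibrillin with medium values under the floor of 2.78, rose by 6.02 ± 0.21 (log2, SE, limma adjusted p = 7.22e-10). The stress-induced transcription factor ATF3 (probe set 202672_s_at) rose from 5.10 ± 0.28 to 10.93 ± 0.049 (SD, n = 3), or 56.7-fold. RGCC, a cell cycle regulator, rose 35.7-fold and the homeobox gene DLX2 46.8-fold. CXCL8 rose by 4.87 from a medium mean of 2.14 ± 0.17, also under the floor, and TNFAIP3 rose 19.6-fold, whereas CCL20 fell 1.79-fold. PTGS2 rose 4.87-fold and PTGS1 fell 3.63-fold. AQP10, with treated values under the floor, changed by -6.14, LGALS14 by -5.41, TNFSF10 by -4.76, SLC2A5 by -4.63 and SLC51A by -4.56. TJP1 rose by 1.29 and CLDN1 changed by -0.28, while OCLN, at 0.067, missed the threshold (adjusted p = 0.316), and 1 of its 3 other probe sets was called lower. limma called 7605 genes, 4311 higher and 3294 lower, of which 2187 changed at least 2-fold.

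By list, 30 of 34 measured members were higher and 1 lower (31 and 1 adjusted over the list alone) among immediate early genes with E. coli supernatant. Those higher included DUSP1 at 2.64, CCN1 at 3.23 and DUSP4, which rose 16.0-fold. Of NF-kB and chemokine genes 15 of 21 measured members were higher and 1 lower (15 and 1 adjusted over the list alone), with NFKBIE at 4.15 and NFKB1 at 3.13. Of oxidative stress genes under NRF2 16 of 23 measured members were higher and 4 lower (16 and 4 adjusted over the list alone), with SQSTM1 at 2.69 and TXNRD1 at 1.86. Cholesterol synthesis genes went down together: 14 of 19 measured members were lower and 0 higher (14 and 0 adjusted over the list alone), with LSS at -1.63 and FDPS at -1.33. Among metallothioneins and zinc transporters 7 of 9 measured members were lower and 2 higher (7 and 2 adjusted over the list alone), with MT1F at -2.75 and MT2A at -1.87. For hypoxia and glycolysis 27 of 35 measured members were lower and 7 higher (28 and 7 adjusted over the list alone), and for lipoprotein assembly and lipid absorption 14 of 18 measured members were lower and 2 higher (14 and 2 adjusted over the list alone). In this order camera gave adjusted p = 1.54e-09, 4.50e-05, 6.13e-04, 1.17e-05, 6.35e-04, 3.13e-06 and 3.96e-05. With an estimated correlation these became adjusted p = 0.0909, 0.0909, 0.224, 0.0909, 0.157, 0.206 and 0.157, and none of the 17 lists camera called in this comparison held. For the NF-kB and cholesterol lists the estimated correlations, -0.0052 and -0.0096, lay below the preset 0.01. Their unadjusted camera p still rose from 6.42e-06 to 0.00779 and from 1.00e-06 to 0.00602. Correlation within the list therefore does not explain these losses, in a fit with 4 residual degrees of freedom against 7 in the probiotic set.

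**Figure D4:**
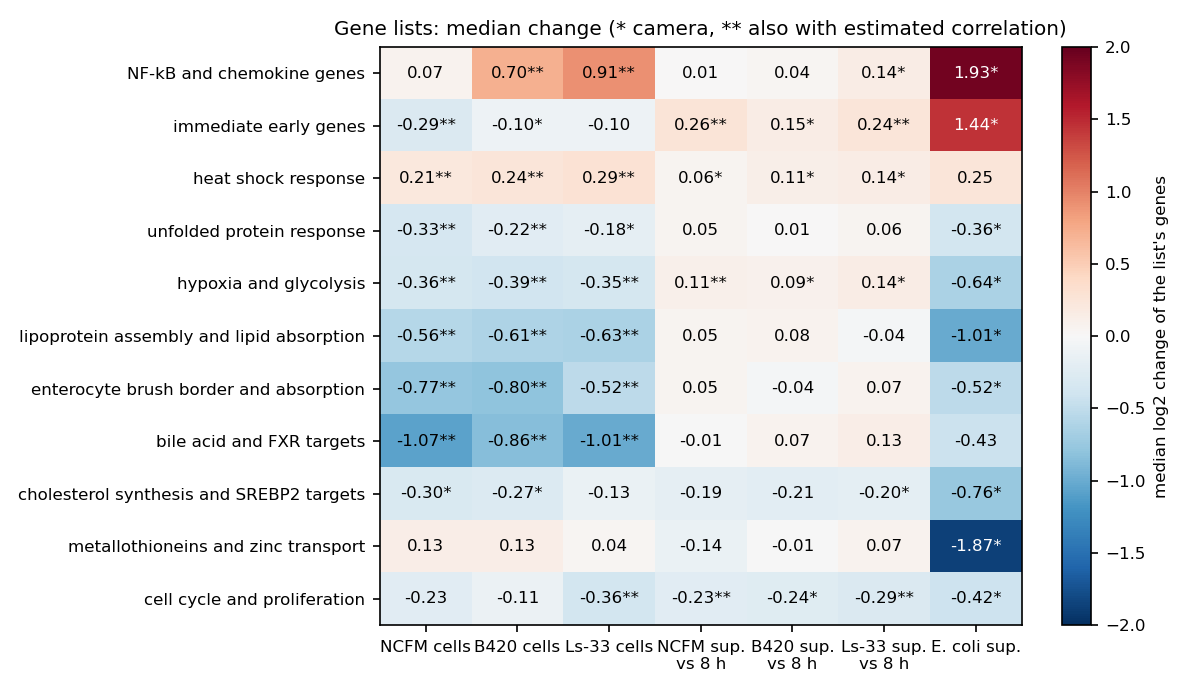
Median log2 change of the measured members of 11 fixed gene lists (rows) in 7 comparisons (columns), printed in each cell and coloured from blue (lower) to red (higher). One star marks a camera adjusted p under 0.05 and a pair of stars a call that also held with an estimated correlation; the NF-kB list has medians of 0.066, 0.70 and 0.91 with NCFM, B. lactis 420 and Ls-33 cells and 1.93 with E. coli supernatant.

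The media themselves differed between 24 h and 8 h in 6611 genes, 3195 higher and 3416 lower at 24 h, but they also belong to different array sets with 1 and 5 µg of RNA. Of cell cycle genes 29 of 40 measured members were higher and 2 lower (29 and 2 adjusted over the list alone) in the 24 h medium, with camera adjusted p = 8.38e-07 and adjusted p = 0.121 with an estimated correlation. Metallothionein and zinc transport genes were higher too, where 7 of 9 measured members were higher and 2 lower (7 and 2 adjusted over the list alone), with adjusted p = 0.00548, and adjusted p = 0.121 with an estimated correlation. Of 2943 genes with at least 2 probe sets called between the media, 33.6% had called probe sets of opposite direction, against 15% of 3282 genes with E. coli supernatant. The share was 16.7% with NCFM cells, 9.80% with B. lactis 420 cells and 8.54% with Ls-33 cells. For the supernatants against 8 h medium it was 3.29%, 7.67% and 4.22% in the same order of strains.

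**Figure D5:**
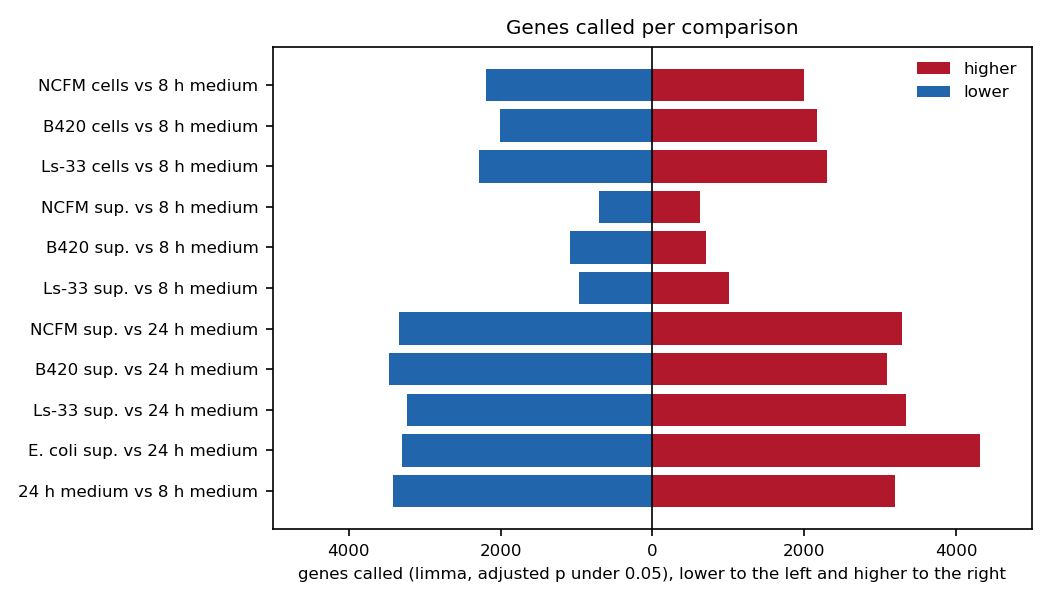
Number of genes called by limma (adjusted p under 0.05) in 11 comparisons, higher to the right and lower to the left of 0. Supernatants gave 1336 to 1972 calls against 8 h medium and 6564 to 6632 against 24 h medium, which differs in array set.

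How alike the responses were was measured across all tested genes, which are not independent replicates. Changes with NCFM and B. lactis 420 cells correlated at r = 0.87, NCFM with Ls-33 at 0.77 and B. lactis 420 with Ls-33 at 0.88. Unchanged groups simulated against the same medium arrays gave r = 0.50. The covariance of changes was 0.19, 0.19 and 0.22 against 0.012 simulated. NCFM and B. lactis 420 cells shared 1491 higher and 1561 lower genes, SLC2A5 and MTTP among the lower, where independent lists would share 365.7 and 371.0. The 2 control arrays were not split between the strains, so part of the excess may come from them. For the covariance of changes the simulated part from shared controls, 0.012, was small beside 0.19 to 0.22. The overlap of calls was not simulated. The supernatants correlated with each other at 0.81 to 0.83, with covariances of 0.061 to 0.067. They share the medium arrays, the difference in time and the kind of broth. Effects of these cannot be told apart from a likeness of the strains' products. Each co-culture correlated with the supernatant of its own strain at 0.20 for NCFM, 0.22 for B. lactis 420 and 0.42 for Ls-33. The 0.50 of simulated unchanged groups comes from the shared medium arrays alone. It is no reference for groups whose genes change, so a lower r does not mean less agreement than unrelated responses. Changes had the same sign in 58.6%, 58.3% and 66.3% of genes, where the simulated 66.6% to 66.7% has the same limit. The covariances of 0.025, 0.030 and 0.064 all lay above the 0.012 simulated. E. coli supernatant shares no control array with the co-cultures and correlated with them at 0.26, 0.36 and 0.43 in the order NCFM, B. lactis 420 and Ls-33. It shared 927, 1166 and 1364 higher genes with them, where independent lists would share 704.7, 771.0 and 818.3, and 1060, 1086 and 1235 lower genes, where they would share 609.8, 558.1 and 636.4. Likeness to E. coli supernatant was not limited to live bacteria. Its correlations with the probiotic supernatants against 8 h medium, also without a shared control array, were 0.28, 0.22 and 0.31. With these it shared 369, 374 and 571 higher genes, where independent lists would share 220.8, 252.0 and 356.3. The lower genes shared were 446, 587 and 571, against 199.0, 306.5 and 271.1.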

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

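The tests of time and of RNA input behind the gap between media, and both tests of the actin difference, were chosen only after the result they address was seen; the tests of signal level, of low signal and of other splits were set beforehand. Strain differences that depended on format had their largest values, on the log2 scale by the interaction test, for CASP5 (4.87), LRG1 (4.71), MIR146A (4.59), CEACAM7 (4.50), OLR1 (4.27), PI3 (3.90), CXCL10 (3.77), KYNU (3.74), ICAM1 (3.19), NNMT (3.13), C3 (3.09) and EGLN3 (2.97), with limma adjusted p from 1.17e-10 for ICAM1 to 5.25e-05 for KYNU. MIR146A and CXCL10 lay under the floor in every supernatant, so their sizes are not well measured. EGLN3, an oxygen-sensing hydroxylase, averaged 6.60 ± 0.28 in 8 h medium, 4.44 ± 0.20 with NCFM cells and 7.18 ± 0.0027 with Ls-33 cells (log2, SD, n = 2).

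The gene count with E. coli supernatant was 7605, and the highest count among the other splits of the 6 arrays was 0. Only 1 of the 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The other splits put medium and supernatant arrays together in each group, which widens the spread within groups. Their low counts therefore say little, and no conclusion is drawn from them.

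The media at 24 h and 8 h differed in 6611 genes. Time in culture as the whole cause is argued against by the probiotic supernatants, also taken at 24 h. Over 6505 of these genes they showed a median of 0.0748 to 0.112 of the change between media, with quartiles no lower than -0.18 and no higher than 0.39 in any of the 3, unless the supernatants offset an effect of time on most genes. RNA input or array set remains open as a candidate explanation. Genes had probe sets called in opposite directions 2.24 times as often between the media as with E. coli supernatant inside 1 set.

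Among genes tested in both, 1336 were lower in all 3 co-cultures, 3219 were lower with E. coli supernatant and 822 were lower in both, SLC2A5, AQP10 and TNFSF10 among them. A shared signal level is argued against, since the overlap was 2.03 times the 404.5 genes of independent lists within classes of mean signal. Loss of 5' signal, seen as the wider actin difference, cannot be told apart from an effect of the bacteria. The supernatants, whose actin shift was 53.7% of that of the co-cultures, showed 0.233 to 0.267 of the co-cultures' median fall over these genes, a range on both sides of the bound written for this test. They share the 8 h medium arrays by which the falls were picked. With E. coli supernatant the median change over these genes was -0.90, against -0.73 to -0.63 in the co-cultures. Its actin difference averaged 2.17 against 2.00 in its medium, with arrays that overlap, and its GAPDH difference was wider too. A biological response common to live bacteria and pathogen products, as the design's groups would allow, stays open and untested beyond this.

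Genes that RefSeq does not list as protein-coding were, of 650 tested, higher in 147 and lower in 51 cases with NCFM cells, 127 and 61 with B. lactis 420 cells and 97 and 80 with Ls-33 cells. Low signal is argued against for NCFM and B. lactis 420 only. Their counts higher were at least 1.73 times those at the share of protein-coding genes of the same signal, 70.5 and 73.6. For Ls-33 the ratio was 1.23, which leaves low signal open there. Loss of 5' signal is left open. The supernatants showed only 0.0574 to 0.0933 of the median rise while carrying 37.4% to 45.8% of the actin shift with NCFM and 61.4% to 75.3% of that with B. lactis 420, which speaks against it, but their GAPDH shift was -5.99% to 16.0% and -12.2% to 32.7% of those, so they do not clearly share the loss. No biological explanation was tested.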

How the results depend on the processing

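No filter, the stricter filter, only the groups compared, quantile normalization and all 20 arrays in 1 fit left every gene count within 1.5 times its value. Without a variance trend counts fell to 942 (among co-cultures), 756, 1121 and 1281 (supernatants of NCFM, B. lactis 420 and Ls-33 against 8 h medium), 0 (among supernatants), 146 (format) and 437 and 584 (NCFM and B. lactis 420 supernatant against both media); the cause was not tested. Testing every probe set raised counts, since more features were tested, to 7661, 7042 and 7503 (co-cultures), 3076 (among them), 13096, 13004 and 13091 (supernatants against 24 h medium), 910 (format), 14083 (E. coli) and 13094 (media). With an estimated correlation 36 of 124 list calls were left. Camera p-values also rose for lists whose estimated correlation lay below the preset 0.01, so lost calls do not by themselves show correlation within lists. Of the lists checked 1 by 1, 81 kept their call with quantile normalization and 8 lost it: tight junction and cholesterol synthesis with NCFM, cholesterol synthesis and TGF-beta with B. lactis 420, ribosomal proteins with E. coli, and NRF2, unfolded protein response and oxidative phosphorylation between media. Simulated unchanged groups gave r = 0.499, which comes from the shared medium arrays alone, where co-cultures gave more. Leaving out 1 array gave 845 to 1565 (among co-cultures), 489 to 863, 789 to 1216 and 771 to 1248 (supernatants against 8 h medium), 3 to 9 (among supernatants), 262 to 655 (format) and 297 to 756, 396 to 951 and 436 to 1078 (both media); other counts stayed within 1.5 times. No named gene with a call turned direction, but CXCL8 with NCFM cells, which had none, went from 0.21 to -0.29. Calls held in every such fit for 127 of 142 named genes with NCFM, 128 of 147 with B. lactis 420, 135 of 146 with Ls-33 and 145 of 148 with E. coli, but for only 54 of 85, 51 of 95 and 66 of 106 with the supernatants of NCFM, B. lactis 420 and Ls-33 against 8 h medium. Replicate numbers did not pair arrays: same-numbered deviations correlated at -0.14, -0.066 and 0.034 in the E. coli set, where 1 of 3 arrays correlated best with its own number, and at -0.11 to 0.059 over 21 pairs of groups in the probiotic set. As a block they gave 4130, 4141 and 4519 genes (co-cultures), 1535 (among them), 1278, 1746 and 1897 (supernatants), 454 (format), 7394 (E. coli), 5523 (media) and 120 list calls; of the lists checked 1 by 1, 86 kept their call and 3 lost it: tight junction with NCFM, and NRF2 and oxidative phosphorylation between media. Genes at the low end of signal limit fold sizes, with 9 named E. coli genes under the floor in 1 group.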

Other observations

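Interferon-stimulated genes differed between Ls-33 and NCFM cells. With Ls-33 cells 9 of 18 measured members were higher and 4 lower (10 and 5 adjusted over the list alone), with OAS3 at 2.45, PARP9 at 2.06 and ISG15 at 0.82, although the list missed the threshold by camera (adjusted p = 0.121). With NCFM cells 3 of 18 measured members were higher and 6 lower (3 and 6 adjusted over the list alone), with OAS3 at 1.28 and IFI27 at -2.42. The list was higher with Ls-33 than with NCFM cells (10 of 18 measured members were higher and 0 lower (10 and 2 adjusted over the list alone); camera adjusted p = 1.18e-04, and adjusted p = 0.0199 with an estimated correlation), in a contrast chosen after the values were seen. With NCFM supernatant against 8 h medium, where time also differs, 5 of 18 were higher and 0 lower (8 and 0 adjusted over the list alone). Camera gave adjusted p = 0.00199 there, and adjusted p = 0.0426 with an estimated correlation. For Ls-33 supernatant these were 0.0146 and 0.0734, and for B. lactis 420 0.229 and 0.294. Among xenobiotic genes, 13 of 20 measured members were lower and 1 higher (13 and 1 adjusted over the list alone) with NCFM, led by UGT1A6 at -2.14 (camera adjusted p = 1.81e-04, and adjusted p = 0.0438 with an estimated correlation). With B. lactis 420 the lower and higher counts were 12 and 0 (12 and 1) and with Ls-33 10 and 3 (12 and 3), with camera adjusted p = 9.46e-05 and 0.00143, and adjusted p = 0.0421 and 0.0891 with an estimated correlation. MMP1, a collagenase, rose by 1.94 with B. lactis 420 and 3.00 with Ls-33 cells. It was also higher by 2.40 and 2.35 with NCFM and Ls-33 supernatant against 8 h medium, but only by 0.54 and 0.49 against 24 h medium. With E. coli supernatant it rose by 1.98. MMP1 values with NCFM cells and with B. lactis 420 supernatant are not given here.

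With E. coli supernatant, targets of p53 and DNA damage genes were higher as a list: 15 of 22 measured members were higher and 2 lower (15 and 2 adjusted over the list alone), with PMAIP1 at 4.31, PLK2 at 3.14 and GADD45B at 2.71 (camera adjusted p = 0.00234, but adjusted p = 0.157 with an estimated correlation). Cell cycle genes were lower, where 25 of 40 measured members were lower and 5 higher (25 and 6 adjusted over the list alone), with TOP2A at -1.29 and KIF20A at -1.57 (adjusted p = 1.35e-04, but adjusted p = 0.256 with an estimated correlation). Among stem and progenitor markers 7 of 10 measured members were higher and 1 lower (7 and 1 adjusted over the list alone), with the Wnt target AXIN2 at 2.03, and camera missed the threshold (adjusted p = 0.114). GLA, the lysosomal galactosidase that degrades the Shiga toxin receptor glycolipid, rose by 1.38 ± 0.059 (SE, limma adjusted p = 3.25e-09). It also rose by 0.41 with Ls-33 cells. Its list, of the synthesis of that glycolipid and related ones, showed no common shift with E. coli supernatant. There 3 of 12 measured members were higher and 5 lower (3 and 5 adjusted over the list alone), with camera adjusted p = 0.645. Of 7 fibroblast and leukocyte markers 1 was higher and 4 lower (camera adjusted p = 0.231). By fry, 27, 28 and 26 of 34 lists were called with NCFM, B. lactis 420 and Ls-33 cells and 30 of 35 with E. coli supernatant. Calls with E. coli included the tight junction list, with 9 members higher and 7 lower, and the prostaglandin list, with 6 and 7. Since fry does not set a list against other genes, these counts may reflect the share of all tested genes that limma called. That share was 35.3%, 35.3%, 38.7% and 64.1% in the same order.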
